A study of Mus musculus with 16 samples.

How the data were processed

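Gene expression was measured by polyA-based RNA sequencing of lumbar dorsal root ganglia, the clusters of sensory neurons beside the spinal cord, from C57BL/6 mouse embryos at embryonic day 13.5. The 16 libraries fall into 4 groups of 4: importin α3 knockouts (KO_alpha3), wild types labelled with that line (WT_alpha3), knockouts of the 3′ untranslated region of importin β1 (KO_beta), and wild types labelled with that second line (WT_beta). Libraries are named by group and by the number in their title. No number is shared between groups and no litter is labelled, so libraries could not be paired, and litters shared between groups are not excluded.

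Per the labels, the deposited values came from a workflow whose submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt, TopHat2 2.0.10, HTSeq 0.6.1p1, DESeq2 1.6.3 and the mouse build mm10, without roles or order. The gene annotation, the strand setting and the filters are not given in the sources used here, so overlapping and antisense genes cannot be separated. The authors deposited whole-number read counts per gene symbol, not normalized, and these counts were the unit of every test with edgeR or DESeq2. The authors also deposited a normalized signal, which equals the count multiplied by 1 constant per library, and it was used in 1 alternative. TopHat2 alignments and gene-level counts leave reads shared between near-identical gene copies uncertain.

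The count table held 24421 gene symbols, of which 3922 had no count in any library. Library totals ran from 19682595 to 26873361 counts. Of the symbols, 24312 (99.6%) were matched to a RefSeq table of the same build, from which chromosome, start and end were taken. Pairs of libraries differed by far more than sampling noise, with a chi-square per degree of freedom of 6.30 to 137 within groups and 5.97 to 145 between groups, so no library was a duplicate of another.

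Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, the filterByExpr filter (minimum count 10, minimum total 15), quasi-likelihood fits and 2-sided tests with Benjamini-Hochberg adjustment at 0.05. The filter kept 15641 genes. Levels are CPM, counts scaled to a common library size, after TMM scaling, given as mean ± SD, and log2 fold changes carry their standard error (SE). Because the series' design text says that the 8 wild types served both projects, each knockout was compared with all 8 in a fit with 3 groups. The wild types of the 2 lines were compared with each other, and the 2 knockout effects with each other, each against its own wild types, in a fit with 4 groups.

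For gene groups, 30 lists were used, covering nuclear transport, neuronal, glial, progenitor, cell cycle, stress and metabolic genes, Hox genes, markers of other cell types that a ganglion dissection could hold, and sex-linked transcripts. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with a correlation estimated per list, and with fry, on log2 CPM with a prior count of 2. Adjustment was over the 30 lists within a comparison, and the result of 1 list is not reported here. List medians are of edgeR log2 fold changes unless named as differences in log2 CPM. Kpna4 and Kpnb1 were also tested with exact 2-sided permutation tests of log2(CPM + 1).

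The groups, designs, alternatives, lists and the rule for named genes were fixed before the data were examined. The rule took Kpna4 and Kpnb1, up to 10 rises and 10 falls among genes past the threshold with an average of at least 1 CPM and with every knockout library on 1 side of the wild-type median, or, where fewer than 5 passed, the 5 genes with the lowest p. It also took the 2 members with the lowest p from each list, or up to 4 where a member passed. For the wild-type comparison and the difference of effects it took 5 rises and 5 falls. Clone names, predicted genes, Xist and Y-linked genes were outside it. The text names part of the genes that the rule gives, and that part was picked after values were seen. Genes outside the rule, marked in the text, were also chosen after their values were seen.

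Alternatives were other sets of wild types, fits with fewer libraries, a Y-linked covariate, other scalings (DESeq2 size factors, upper quartile, library size), other filters, a robust spread, DESeq2 1.42.0, limma-voom, limma-trend on the normalized signal, and leaving out each library in turn. After the data were seen, further alternatives were added: the mean of the progenitor list as a covariate (alone, with the Y-linked covariate, and in DESeq2), 2 surrogate variables from sva 3.50.0, libraries with or without Y-linked reads alone, fits without the 4 libraries highest in the progenitor list or in markers of other cell types, counts near the targeted genes at an unadjusted p under 0.01, and, for Kpnb1 in the β1 comparison, the log2 ratio of the globins Hbb-bh1 and Hbb-y or the mean of the cell cycle list as a covariate. List medians without WT_beta 399 or without these sets of 4 libraries were also taken after the list results had been seen. The contrasts by Y-linked reads came from a fit to all libraries with KO_alpha3 divided by those reads. Knockouts with Y-linked reads were set against WT_alpha3, and those without against WT_beta. Lists of liver and epidermis genes were added after the data were seen and are named as added.

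The steps were tested on simulated counts with 200 genes changed by known amounts. For the α3 comparison, 25.4% of genes changed by 0.5 on the log2 scale, 73.1% of those changed by 1 and 95.5% of those changed by 2 were recovered, with 7 false calls among 136 in 15555 genes. For the β1 comparison the shares were 25.4%, 67.2% and 89.4%, with 2 false calls among 123 in 15548 genes. For the wild types they were 17.9%, 61.2% and 87.9%, with 11 false calls among 122 in 15548 genes. For the difference of effects they were 1.49%, 41.8% and 68.2%, with 1 false call among 75 in 15555 genes. The simulated genes varied independently of each other, while in the real libraries the first principal component held 38.5% of the variance. These rates may therefore not hold for the real data.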

Results

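Lumbar dorsal root ganglia of mouse embryos at embryonic day 13.5 were profiled in 16 RNA libraries, 4 in each of 4 groups. Importin α3 and importin β1 carry proteins into the nucleus: the α subunit binds the nuclear localization signal of the cargo, and β1 brings the complex through the pore. The series asks what loss of importin α3, or of the 3′ untranslated region of the importin β1 transcript, does to peripheral sensory neurons. Total counts per library ran from 22896330 to 24850289 in KO_alpha3, 19682595 to 24026025 in WT_alpha3, 22085189 to 25841307 in WT_beta and 21203919 to 26873361 in KO_beta. The labels do not say that the libraries came from separate embryos, so p-values measure only the spread between these samples, a part of which may be technical. KO_alpha3 held libraries with and without Y-linked reads, so not all of its libraries came from 1 embryo.

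Sex-linked transcripts divided the libraries unevenly over the groups. In 10 libraries the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 100 to 144 CPM and Xist, the RNA of the inactive X chromosome, lay at 0.335 to 3.69 CPM. In the other 6 the Y-linked sum was 0 to 1.18 CPM and Xist 504 to 1001 CPM. All 4 WT_alpha3 and all 4 KO_beta libraries had Y-linked reads, none of the 4 WT_beta libraries had them, and KO_alpha3 was divided 2 and 2. The design text names a gender effect as the reason for using all 8 wild types.

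The targeted importin α3 transcript was nearly lost in the α3 knockout. Kpna4, the gene of importin α3 (chromosome 3, 69067149 to 69127113, mm10), lay at 0.862 ± 0.234 CPM (SD, n = 4) in KO_alpha3 and at 76.6 ± 4.38 CPM (SD, n = 8) in the wild types, or 1.13% of the wild-type level. The 4 knockout libraries held 14 to 27 reads of it, against at least 1348 in each other library. An exact permutation test gave p = 0.00202, the smallest that the 495 splits allow. In KO_beta, Kpna4 was 74.9 ± 0.804 CPM (SD, n = 4), 97.7% of the wild types (exact permutation p = 0.515).

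Kpnb1, the gene of importin β1 (chromosome 11, 97159714 to 97187881, mm10), was not lower in the 3′ untranslated region knockout. It lay at 530 ± 23.0 CPM (SD, n = 4) in KO_beta and 437 ± 49.1 CPM (SD, n = 8) in the wild types (exact permutation p = 0.0121, Benjamini-Hochberg over 4 tests 0.0242), and the lowest KO_beta library was above 7 of the 8 wild types. Against WT_beta, at 423 ± 25.7 CPM (SD, n = 4), all 4 KO_beta libraries were higher (exact p = 0.0286, the smallest possible), while against WT_alpha3, at 450 ± 66.8 CPM, the exact permutation p was 0.114. In edgeR's test over all genes its log2 fold change was 0.28 ± 0.10 with a Benjamini-Hochberg adjusted p of 0.932. A deletion in the untranslated region need not lower a count taken over the whole gene, so this value does not check the labels. In KO_alpha3, Kpnb1 was 514 ± 89.2 CPM (SD, n = 4; exact permutation p = 0.0848).

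**Figure D1:**
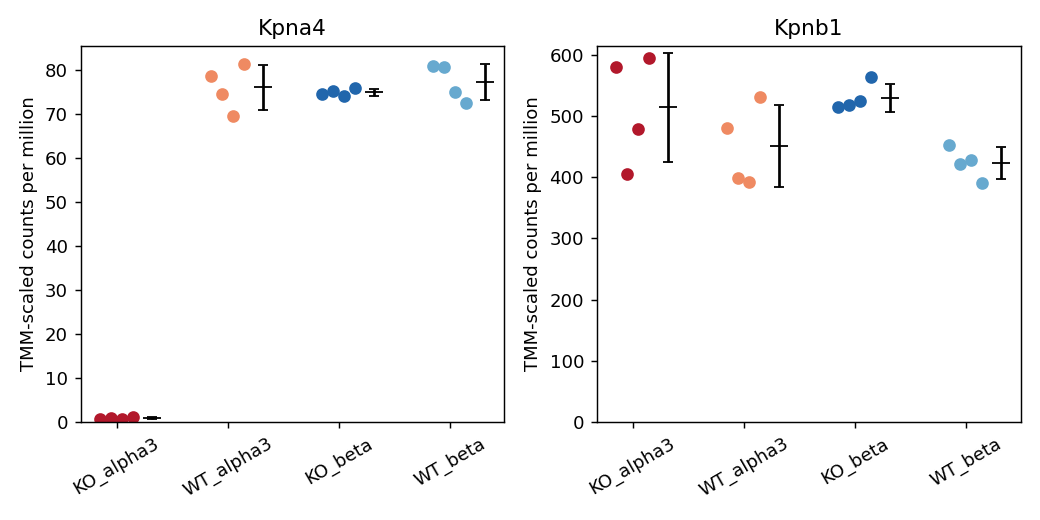
Kpna4 and Kpnb1 in CPM after TMM scaling (vertical axes) for the 4 groups (horizontal axes), with 1 point per library and bars for the mean ± SD of 4 libraries. Kpna4 lies at 0.619 to 1.13 CPM in KO_alpha3 and at 69.5 to 81.4 CPM in the wild types, and the 4 KO_beta libraries lie above the 4 WT_beta libraries for Kpnb1.

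In KO_alpha3 against the 8 wild types, 1 gene of 15641 passed, Kpna4 itself, with a log2 fold change of -6.46 ± 0.13 (edgeR, Benjamini-Hochberg adjusted p = 1.3e-14). Smaller changes in other genes are not excluded by this count. The other importin genes did not pass: Kpna3 was at 0.13 ± 0.05 and Kpna1 at 0.12 ± 0.05 on the log2 scale, both chosen after their values were seen. The 5 genes with the lowest p after Kpna4 had an adjusted p of 0.330 and did not pass. They were Isoc1 at -0.46 ± 0.08, Bche, which encodes butyrylcholinesterase, at 0.46 ± 0.09, Fstl5, which encodes a follistatin-like secreted protein, at -0.81 ± 0.16, Coasy, the enzyme of the last steps of coenzyme A synthesis, at 0.23 ± 0.05, and Lrrc4b, a synaptic adhesion molecule, at -0.96 ± 0.21. Bche and Fstl5 lie within 10 Mb of Kpna4 on chromosome 3. In all, 1696 genes had an unadjusted p under 0.05 (659 higher, 1037 lower), where 782 would be expected by chance. The number was 474 of 15096 genes in a fit to KO_alpha3 and WT_alpha3 alone, and 3297 of 15792 without KO_alpha3 50. It thus depended on the libraries used and is not a count of changed genes.

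Lists of neuronal genes went different ways in KO_alpha3, and no member passed over all genes. Among 25 pan sensory neuron genes, none passed over all genes and 4 were higher adjusted over the list alone, among them the transcription factor Pou4f1 (0.47 ± 0.14) and the neurofilament gene Nefm (0.34 ± 0.10). Among 28 genes of the retrograde injury signalling complex, which carries signals from axon to cell body, none passed over all genes and 2 were higher adjusted over the list alone, the dynactin subunit Dctn1 (0.29 ± 0.08) and the intermediate filament gene Vim (0.33 ± 0.09). Camera at the preset correlation placed both lists higher, each at an adjusted p of 0.00189, and both calls were lost with an estimated correlation (adjusted p = 0.658). The 27 nociceptor lineage genes had a median of -0.091 (camera adjusted p = 0.804), with Tlx3, a nociceptor transcription factor, higher (0.36 ± 0.10) and Sst, which encodes somatostatin, lower (-2.84 ± 0.78) adjusted over the list alone. The 28 mechanoreceptor and proprioceptor genes had a median of -0.12 (camera adjusted p = 0.741), with 1 member, Necab2, higher adjusted over the list alone (0.39 ± 0.10). For 25 axon regeneration genes the median was -0.046 (adjusted p = 0.831), for 24 progenitor and Notch genes 0.30 (0.105), for 25 glial and Schwann precursor genes -0.033 (0.287), and for 34 cell cycle genes -0.011 (0.606). These values moved without WT_alpha3 45 and 79 and WT_beta 399 and 401, the 4 libraries highest in markers of other cell types. All 4 are wild types and had the highest cell cycle means of the wild types (5.53 to 6.56, the others 4.65 to 4.97). Leaving them out therefore raises the cell cycle difference by itself, and KO_alpha3 42 and 81 (5.77 and 5.94) stayed in. The cell cycle median was then 0.72, with 33 of 34 genes higher adjusted over the list alone, the progenitor median 0.71, with 14 of 23 higher, the pan sensory median -0.087, the retrograde -0.025, the nociceptor -0.37, the mechanoreceptor -0.22 and the axon regeneration median -0.25, with 0 members of these 5 passing, and the glial median -0.068, with 3 of 25 higher. Without the 4 libraries highest in the progenitor list, WT_alpha3 45 and 79 and KO_alpha3 42 and 81, which leaves 2 knockouts, all 34 cell cycle genes were negative (median -0.16). The medians were then 0.063 for progenitor, 0.088 for pan sensory, 0.015 for retrograde, 0.11 for nociceptor, 0.030 for mechanoreceptor, 0.022 for axon regeneration and 0.15 for glial genes, with 0 members of any of these lists passing. The retrograde list also had 0 members passing without WT_beta 399.

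Genes of nuclear transport and of general metabolism lay slightly higher in KO_alpha3 by camera at the preset correlation, and every one of these calls was lost with an estimated correlation. Of the 30 nuclear transport genes 26 were positive, with a list median of 0.097 (adjusted p = 0.00878, and adjusted p = 0.658 with an estimated correlation), while the list mean was -0.14 and fry pointed lower, with Kpna4 a member. The 31 nucleoporins had a median of 0.063 (0.0225, then adjusted p = 0.799), 25 cholesterol synthesis genes 0.11 (0.00109, then adjusted p = 0.723), 77 ribosomal proteins 0.071 (0.00114, then adjusted p = 0.799), and 79 respiratory chain genes 0.046 (0.00334, then adjusted p = 0.782). The 24 unfolded protein and heat shock genes had a median of 0.076 (0.0070, then adjusted p = 0.658), with the endoplasmic reticulum chaperone Hyou1 at 0.27 ± 0.09 and Manf at 0.35 ± 0.12. In cholesterol synthesis, Hsd17b7 was at 0.44 ± 0.12 and Srebf2, the transcription factor of the pathway, at 0.19 ± 0.07. None of these members passed over all genes or adjusted over the list alone, Kpna4 aside. Without the 4 libraries highest in other cell types the cholesterol median turned to -0.025, with 11 of 25 positive, and the medians were 0.13 for nuclear transport, 0.19 for nucleoporins, 0.27 for ribosomal proteins, 0.061 for the respiratory chain and 0.14 for unfolded protein genes, of which 9 of 24 were higher adjusted over the list alone. Without the 4 highest in the progenitor list the same 6 medians were 0.033, 0.028, -0.0049, 0.020, 0.0083 and 0.10, with 0 unfolded protein genes passing.

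Markers of tissues around the ganglion lay lower in KO_alpha3 than in the 8 wild types, of which WT_alpha3 45 and 79 and WT_beta 399 and 401 were the highest of all 16 libraries in such markers. All 21 skeletal muscle genes were negative, with a median of -1.60, and 19 passed adjusted over the list alone, among them the troponin Tnnt1 (-1.54 ± 0.49) and titin, Ttn (-2.23 ± 0.72). Of 23 spinal cord genes 22 were negative, with a median of -2.23, and 11 passed adjusted over the list alone, among them the GABA transporter Slc32a1 (-3.58 ± 0.81) and the interneuron transcription factor Pax2 (-3.38 ± 0.87). All 9 Hox genes of paralogue groups 10 to 13, which mark caudal levels of the body and not a tissue, were also negative. Their median was -1.66, and 3 passed adjusted over the list alone, among them Hoxc11 (-4.40 ± 1.41). None of these members passed over all genes. Hoxa10, named after its values were seen, was 0.877 CPM in KO_alpha3 81, 4.38 in WT_alpha3 79 and 1.89 in WT_beta 399. In every other library it was 22.5 to 84.4 CPM. Its mean was 43.5 CPM in KO_alpha3, 32.9 in WT_alpha3 and 60.1 in WT_beta. Whether single libraries held other body levels was not tested. Camera's adjusted p was 1.67e-15 for muscle, 1.89e-11 for spinal cord and 0.0070 for these Hox genes, and all were lost with an estimated correlation (adjusted p = 0.658 for each). The same held for 18 macrophage genes (median -0.48, 6.12e-08), all negative, with Csf1r at -0.47 ± 0.17 and Cx3cr1 at -0.40 ± 0.14, and for 22 fibroblast and meninges genes (median -0.35, 2.82e-05), with Dcn at -0.65 ± 0.25, both again at an adjusted p of 0.658 with an estimated correlation. For 17 sympathetic ganglion genes the median was -1.92 (0.0311, then adjusted p = 0.782 with an estimated correlation). For 11 erythroid genes it was -1.21 (0.189), for 13 cartilage genes 0.046 (0.655) and for 20 endothelium and pericyte genes -0.0058 (0.770). In the added lists, all 15 epidermis genes were negative (median -2.09) and 14 passed adjusted over the list alone, with an unadjusted fry p of 0.000374, and all 14 liver genes were negative (median -3.49), 13 adjusted over the list alone, with a fry p of 0.157. The liver gene Alb was at 1740 CPM in WT_beta 399 and at most 142 CPM in the other wild types, and without WT_beta 399 the liver median was -1.50 with 0 members passing. The sympathetic gene Dbh was at 152, 74.3 and 64.5 CPM in WT_alpha3 45, WT_alpha3 79 and WT_beta 401, and at most 7.96 CPM in the other wild types; both genes were named after their values were seen. Without the 4 libraries highest in other cell types the medians were -0.81 for muscle, -1.59 for spinal cord, -0.15 for macrophages, -0.22 for fibroblasts and -1.21 for epidermis, and turned to 0.86 for sympathetic and 0.27 for erythroid genes. Adjusted over the list alone, 0 muscle and 0 spinal cord genes, 0 liver genes, 2 of the 6 caudal Hox genes left (median -1.71) and 11 of 15 epidermis genes were then lower, and 2 erythroid genes were higher. The liver median was -0.94, the cartilage median 0.095, with 1 of 12 genes higher, and the endothelium median -0.025. Without the 4 libraries highest in the progenitor list, 0 muscle, spinal cord, caudal Hox, liver and epidermis genes passed adjusted over the list alone, with medians of -0.88, -2.93, -1.97, -3.08 and -1.39, and 9 of 15 cartilage genes were higher (median 0.70). The other medians were then -0.21 for macrophages, -0.11 for fibroblasts, -1.05 for sympathetic, -0.67 for erythroid and -0.038 for endothelium genes.

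Signalling lists were near 0 or slightly negative. The 101 voltage gated channel genes had a median of -0.13 (camera adjusted p = 0.0109, then adjusted p = 0.782 with an estimated correlation), with the potassium channel Kcnj2 at -0.95 ± 0.26. The 27 AP-1 and immediate early genes had a median of -0.10 (0.0697), with Nr4a3 at -1.06 ± 0.32, and the 28 integrated stress response genes -0.091 (0.141). The 23 p53 target genes had a median of 0.037 (0.287), and Perp, which also serves in desmosomes of epithelia, was the 1 member lower adjusted over the list alone (-1.31 ± 0.30). The 19 Hox genes of groups 4 to 9 had a median of 0.0028 (0.287) and the 5 sex-linked transcripts 0.20 (0.957). Without the 4 libraries highest in other cell types the medians were -0.39 for channels, -0.21 for AP-1, -0.047 for integrated stress, 0.063 for p53 (2 members higher and 2 lower adjusted over the list alone), 0.44 for Hox groups 4 to 9 (1 higher) and 0.18 for sex-linked transcripts. Without the 4 highest in the progenitor list they were 0.033, -0.033, -0.093, 0.058, -0.031 and 1.79, with 1 sex-linked member lower and 0 others passing. The median, mean or direction of a test differed in sign in the nuclear transport, glial, cell cycle, p53, endothelium and sex-linked lists. In fry, no list of the 30 passed.

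The count of genes in the α3 comparison depended on the tool and on the libraries. DESeq2 called 128 genes (26 higher, 102 lower), with 8 of the 23 spinal cord genes and 10 of the 15 added epidermis genes among the lower ones; leaving out KO_alpha3 50 gave 124 calls in edgeR (66 higher, 58 lower), and the libraries without Y-linked reads alone gave 692 (331 higher, 361 lower). The last contrast set KO_alpha3 42 and 81, the 2 knockouts highest in the progenitor list, against WT_beta. The libraries with Y-linked reads, KO_alpha3 50 and 75 against WT_alpha3, gave 1 call, Kpna4. The line of the wild types thus changed together with the Y-linked reads. Kpna4 passed in each of these settings.

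**Figure D2:**
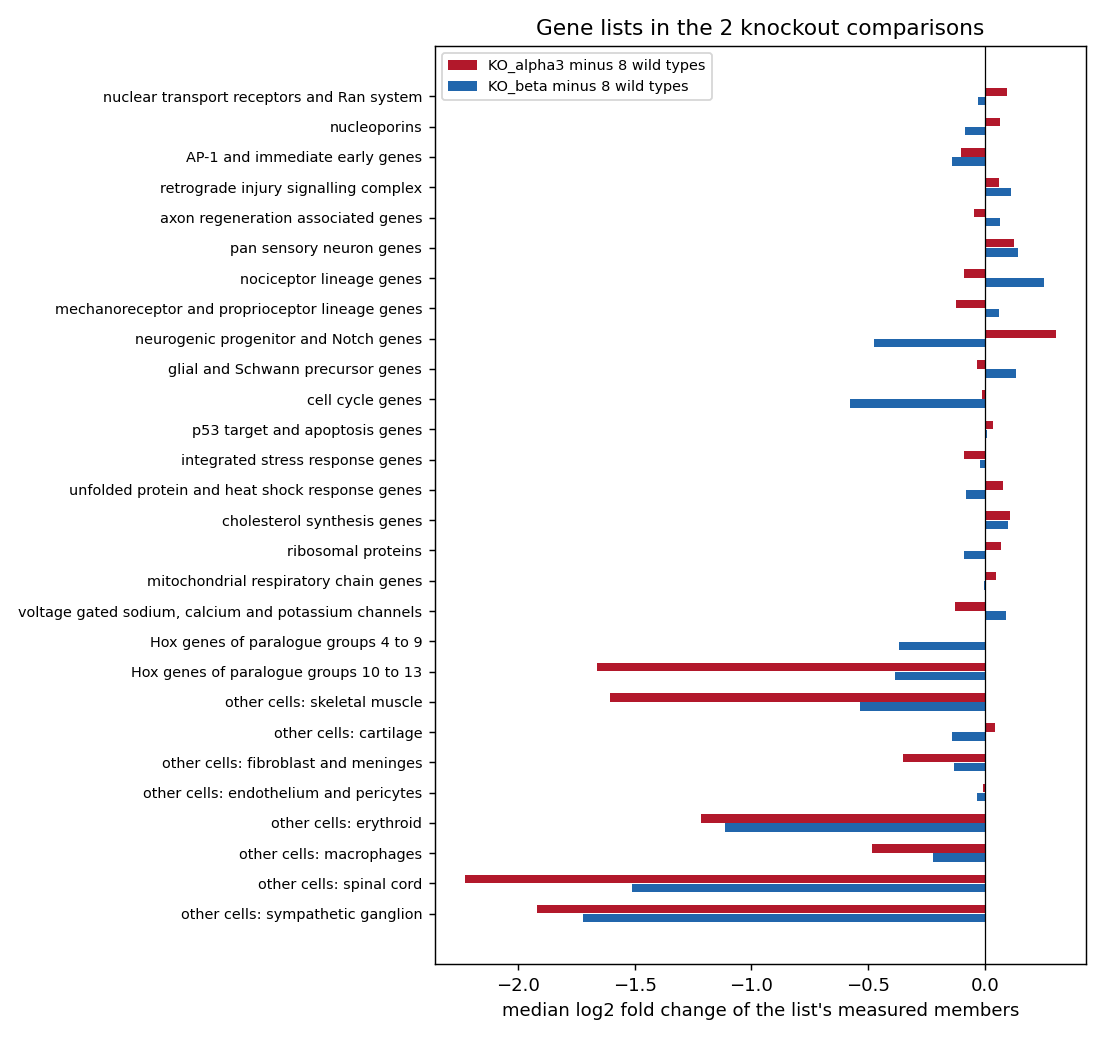
Median log2 fold change of the measured members (horizontal axis) of 28 gene lists (vertical axis, the sex-linked list and 1 other left out) for KO_alpha3 and for KO_beta, each against the 8 wild types. Bars give the median only, without an error. The spinal cord list has a median of -2.23 in KO_alpha3 and -1.51 in KO_beta, and the cell cycle list -0.011 and -0.58.

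In the β1 3′ untranslated region knockout, cell cycle and progenitor genes lay lower than in the 8 wild types. Nociceptor and pan sensory neuron genes lay slightly higher, without any gene passing. All 34 cell cycle genes were negative, with a median of -0.58, and 22 of 24 progenitor and Notch genes were negative, with a median of -0.47. The 27 nociceptor lineage genes had a median of 0.25, with 19 positive, and the 25 pan sensory neuron genes 0.14, with 20 positive. Examples are the cyclins Ccne1 (-0.64 ± 0.27) and Ccnd1 (-1.14 ± 0.52), the neurogenic factor Neurog2 (-2.30 ± 0.81), and the sodium channel Scn9a (0.37 ± 0.20). Camera's adjusted p at the preset correlation was 1.42e-10 for cell cycle, 0.00084 for progenitor, 0.00323 for nociceptor and 0.000641 for pan sensory genes, and each call was lost with an estimated correlation (adjusted p = 0.574). The mean log2 CPM of the cell cycle list was 6.02 and 6.56 in WT_alpha3 45 and 79, 5.89 in WT_beta 399 and 5.53 in WT_beta 401. In the other wild types it was 4.65 to 4.97, and in KO_beta 4.71 to 5.10. All 11 erythroid genes were negative in KO_beta (median -1.11). Without WT_alpha3 45 and 79 and WT_beta 399 and 401, the 4 libraries highest in other cell types, the cell cycle median turned to 0.16, with 33 of 34 positive. The progenitor median was then 0.0015, and the nociceptor and pan sensory medians turned to -0.024 and -0.046. Those 4 were also the wild types highest in the cell cycle list, so leaving them out raises the cell cycle difference by itself. Without the 4 libraries highest in the progenitor list, 2 of which are wild types, the directions stayed: all 34 cell cycle genes were negative (median -0.20), and the medians were -0.083 for progenitor, 0.066 for nociceptor and 0.045 for pan sensory genes.

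Of 15641 genes, edgeR called 0 in KO_beta against the 8 wild types, and 349 had an unadjusted p under 0.05, where 782 would be expected by chance. DESeq2 called 1 gene, Xist, named here after its value was seen, and limma-voom and limma-trend called 0 each. The 5 genes with the lowest p, all at a Benjamini-Hochberg adjusted p of 0.932 in edgeR, were Unc45a, a myosin chaperone (0.20 ± 0.05), Rnaset2b, a ribonuclease (-0.68 ± 0.18), Abca4, a lipid transporter (-0.52 ± 0.15), Sfi1, a centrosome protein (0.39 ± 0.11), and Sulf1, a heparan sulfate sulfatase (-0.75 ± 0.23). The 8 libraries of the β line alone gave 7 calls, all of them sex-linked genes. There all KO_beta and no WT_beta libraries had Y-linked reads. The wild types of the other line as controls gave 4, 1500015A07Rik, Gm3893, Zfp932 and Mtg1, and the mean of the wild-type groups 2, the first pair. These genes are named here after the calls were seen. The first 3 are those called below between the wild types of the 2 lines. In them KO_beta differed from WT_beta by at most 0.34 on the log2 scale.

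Other lists passed camera at the preset correlation in KO_beta, and all were lost with an estimated correlation. Higher were the retrograde signalling complex (median 0.11, adjusted p = 0.000105), cholesterol synthesis with Nsdhl at 0.27 ± 0.13 (median 0.10, 0.000209), glial and Schwann precursor genes with Cnp at 0.30 ± 0.17 (median 0.14, 0.00696) and sex-linked transcripts (median 1.12, 0.0350), each at an adjusted p of 0.574 with an estimated correlation. Lower were spinal cord with Lhx5 at -2.20 ± 0.84 (median -1.51, 1.42e-10), macrophages (median -0.22, 0.000262), fibroblast and meninges (median -0.13, 0.0113), sympathetic ganglion (median -1.72, 0.00323) and Hox groups 4 to 9 (median -0.37, 0.00525), each likewise at an adjusted p of 0.574. Nucleoporins (median -0.086, 0.00118) and skeletal muscle (median -0.54, 0.00061) came to an adjusted p of 0.576, and ribosomal proteins (median -0.088, 0.000115) to an adjusted p of 0.741. Of these medians, 7 turned sign without the 4 libraries highest in other cell types: retrograde -0.024, cholesterol -0.014, macrophages 0.11, sympathetic 0.55, nucleoporins 0.036, muscle 0.21 and ribosomal 0.088, with 77 of 77 positive. The others were 0.027 for glial, 1.24 for sex-linked, -0.34 for spinal cord, -0.046 for fibroblast and -0.012 for Hox genes of groups 4 to 9. All 4 libraries left out were wild types chosen by markers of other cell types, so leaving them out raises the differences in such markers by itself. Without the 4 highest in the progenitor list no median turned, with 0.014 for retrograde, 0.048 for cholesterol, 0.069 for glial, 1.84 for sex-linked, -1.23 for spinal cord, -0.20 for macrophage, -0.14 for fibroblast, -0.81 for sympathetic, -0.080 for Hox, -0.021 for nucleoporin, -0.50 for muscle and -0.0024 for ribosomal genes. Adjusted over the list alone, 1 member passed in all 30 lists with all 16 libraries, the sex-linked transcript Xist. In fry, no list passed. The nuclear transport list had a median of -0.030 (adjusted p = 0.466), which turned to 0.031 and came to -0.0018 in these 2 fits. In the fit without the 4 highest in the progenitor list, 1 nuclear transport and 1 retrograde member were higher adjusted over the list alone. The median, mean or direction of a test differed in sign in the axon regeneration, p53, channel, respiratory chain, Hox groups 10 to 13 and sex-linked lists.

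Between the wild types of the 2 lines, pooled above, edgeR called 3 genes. The noncoding RNA 1500015A07Rik (chromosome 18, 61726390 to 61728254, mm10) was higher in WT_alpha3, with a log2 difference of 2.01 ± 0.15 (edgeR, Benjamini-Hochberg adjusted p = 1.52e-05). Gm3893, a transcribed pseudogene whose reads may be shared with other copies (chromosome 4, 42089373 to 42092930), was lower, at -5.27 ± 0.40 (adjusted p = 1.68e-05), and so was the zinc finger gene Zfp932 (chromosome 5, 109996502 to 110012266), at -1.19 ± 0.17 (adjusted p = 0.0301). The first pair have clone or predicted names and were named after their values were seen. Genes next in p did not pass: Mtg1 was at -0.69 ± 0.12, the co-chaperone Bag3 at 0.68 ± 0.12, Itfg2 at -0.42 ± 0.08, Rab3gap1 at 0.57 ± 0.11 and Efcab7 at 1.24 ± 0.25. DESeq2 called 29 genes, and fits without the 4 libraries highest in the progenitor list called 321 (252 higher, 69 lower). Of the 8 fits that left out 1 wild type, 1 kept all 3 calls, the fit without WT_alpha3 45. Zfp932 was not called in the fits without WT_alpha3 54, 55 or 79 or WT_beta 399, 401, 410 or 415, with 3 calls without WT_beta 415 and 2 in each of the others.

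Among the lists, sex-linked transcripts set the wild types apart, with a median of 8.29 (fry adjusted p = 0.0258), 0 members passing over all genes and 5 of 5 adjusted over the list alone, 4 higher and 1 lower. Camera's adjusted p for this list was 3.66e-05, lost with an estimated correlation (adjusted p = 0.111). Camera at the preset correlation also placed nuclear transport genes (median 0.089, 0.00475), nucleoporins (0.086, 0.0109), progenitor genes (0.46, 0.0380), unfolded protein genes (0.11, 0.00475) and Hox groups 4 to 9 (0.45, 0.000234) higher in WT_alpha3, and skeletal muscle (-0.59, 0.00475) and macrophages (-0.21, 0.0133) lower. With an estimated correlation the unfolded protein and Hox lists came to an adjusted p of 0.772 and the other lists to an adjusted p of 0.944. In the unfolded protein list 1 member, Bag3, was higher adjusted over the list alone. On the log2 CPM scale that camera reads, the median went from 0.23 to 0.025 for the progenitor list and from 0.065 to -0.032 for the nucleoporin list without WT_alpha3 79, and camera then pointed lower for both. The median, mean or direction of a test differed in sign in the pan sensory, mechanoreceptor, glial, channel and spinal cord lists.

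For the effects of the 2 knockouts, each against its own wild types, edgeR called 1 gene as different. Kpna4 had a difference of -6.41 ± 0.16 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 5.84e-12). For Kpnb1 the difference was -0.13 ± 0.17 (adjusted p = 0.996). The sex-linked list differed, with a median of -9.26, and kept its call with an estimated correlation (adjusted p = 0.0272) and in fry (adjusted p = 0.0137). Camera at the preset correlation also called cell cycle genes (median 0.22, 0.000936) and ribosomal proteins (0.093, 0.000103) higher, and channels (-0.31, 0.0232) and skeletal muscle (-0.43, 0.0478) lower, all at an adjusted p of 0.935 with an estimated correlation. With the Y-linked covariate, which divides the β line as its groups do, camera at the preset correlation called all 4 the other way. Their medians in log2 CPM went from 0.32 to -0.86 for cell cycle (adjusted p = 4.81e-05), 0.11 to -0.28 for ribosomal (adjusted p = 3.57e-07), -0.24 to 0.58 for channel (adjusted p = 8.26e-05) and -0.74 to 1.77 for muscle genes (adjusted p = 0.000432). The X-linked genes Kdm6a (0.89 ± 0.18) and Eif2s3x (0.98 ± 0.22) and the adhesion adaptor Fblim1 (-0.84 ± 0.23) were among the genes with the lowest p and did not pass. Adjusted over the list alone, Kpna4 was lower in its list, 1 sex-linked member was higher and 4 were lower, and 1 member of the added epidermis list was lower. The median, mean or direction of a test differed in sign in the nuclear transport, pan sensory, unfolded protein, respiratory chain, macrophage and added liver lists. DESeq2 called 6 genes, and edgeR called 3 without KO_alpha3 50 and 2 without KO_alpha3 75. Apart from Kpna4, all of these were X- or Y-linked. They were Xist in each, Kdm6a in DESeq2 and without KO_alpha3 50, and Eif2s3y, Ddx3y and Kdm5d in DESeq2.

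The comparisons of the 2 knockouts with the same 8 wild types shared no called gene, and could share none, since the β1 comparison had no calls. At an unadjusted p under 0.01 they shared 12 genes in the same direction, 3 higher and 9 lower, where independent lists would share 0.115 and 0.514, and groups simulated without any effect against the same wild types shared 12.1 on average (5 to 17 in 20 simulations). Each knockout against its own wild types gave 1 such gene and 2 in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had r = 0.57 and a covariance of 0.0921, where the simulated groups gave r = 0.32 (0.29 to 0.35) and a covariance of 0.0249. The share of genes with the same sign went the other way, at 52.2% against 60.9% (60.1% to 61.5%) in the simulated groups. The simulated genes varied independently of each other, unlike the real ones, so the simulated ranges do not bound what a structure of the samples alone can give. Against own wild types the values were r = 0.42 and 0.0686. On log2 CPM, r was 0.31 with the 8 shared wild types and 0.059 on average over 36 divisions of the wild types into 2 sets of 4, 1 per knockout (-0.39 to 0.43), with covariances of 0.0304 and 0.00147.

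No gene near either targeted gene was called. Within 20 Mb of Kpna4, 0 of 177 tested genes passed in the α3 comparison, and 0 of 567 within 20 Mb of Kpnb1 passed in the β1 comparison (edgeR). No gene elsewhere was called either, Kpna4 aside, so these counts cannot tell whether genes near the targets differ. At an unadjusted p under 0.01, 8 of the 177 and 418 of 15424 genes elsewhere were counted (Fisher's exact p = 0.156). Bche and Fstl5, among the genes with the lowest p in the α3 comparison, were among the 8 and lie within 10 Mb of Kpna4. Within 10 Mb, 3 of 47 genes were counted (Fisher's exact p = 0.137). DESeq2 called Bche and Fstl5 over all genes. A local effect of the targeted locus on them was not told apart from the loss of importin α3. The numbers near Kpna4 were 23 of 510 within 40 Mb (Fisher's exact p = 0.0180) and 6 of 177 against own wild types (Fisher's exact p = 0.0314). Around Kpnb1, in the same α3 comparison, 23 of 567 were counted (Fisher's exact p = 0.0640). In the β1 comparison 1 of 567 genes near Kpnb1 was counted (Fisher's exact p = 1).

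In the α3 line the libraries of a group differed in progenitor and nociceptor genes by more than the group means did. The mean log2 CPM of the progenitor list ran from 3.53 to 4.92 in KO_alpha3, from 3.30 to 5.29 in WT_alpha3, from 3.70 to 4.44 in WT_beta and from 3.53 to 3.92 in KO_beta. Neurog1, which starts neurogenesis in the ganglion, lay at 92.6 CPM in KO_alpha3 81 and 2.68 CPM in KO_alpha3 50. Trpv1, the heat and capsaicin receptor of nociceptors, lay at 5.47 and 152 CPM in the same libraries. KO_alpha3 81 had no Y-linked reads and KO_alpha3 50 had them, so this pair also differs in sex. The first principal component held 38.5% of the variance and ran from -41.2 in WT_alpha3 55 to 73.3 in WT_alpha3 79, both wild types of one line.

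**Figure D3:**
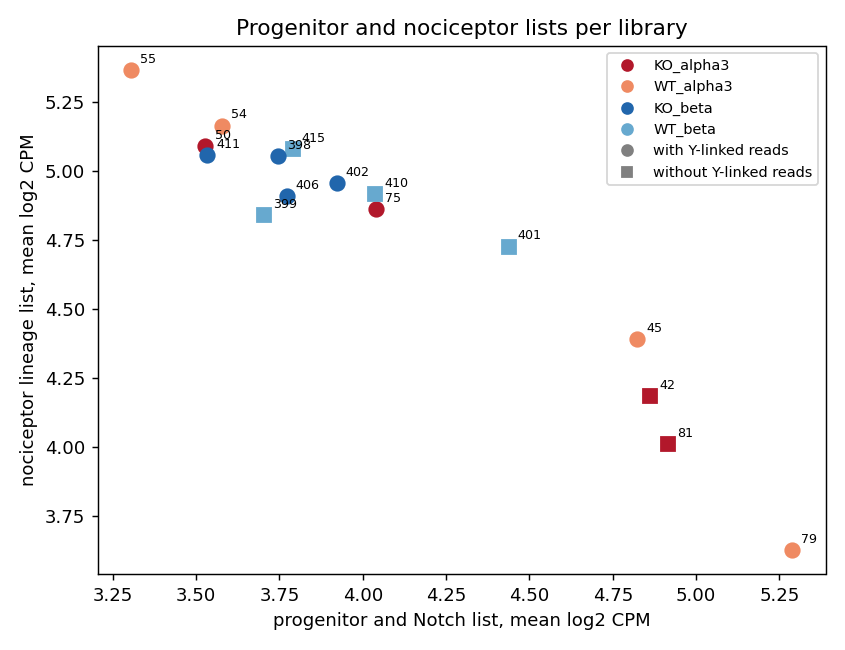
Mean log2 CPM of the neurogenic progenitor and Notch list (horizontal axis) and of the nociceptor lineage list (vertical axis), 1 point per library, with color for the group and circles for libraries with Y-linked reads. WT_alpha3 45 and 79 and KO_alpha3 42 and 81 lie at 4.82 to 5.29 on the progenitor list, and the other 12 libraries at 3.30 to 4.44.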

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

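The test of the differences between the knockout effects below was planned. The library checks covered list means, library totals and genes of the text, a set picked after values were seen. The tests of sex, maturity, spinal cord tissue and batch were chosen only after the results they bear on had been seen. So were the counts of other splits.

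Single libraries stood far from the other 3 of their group in 16 of 400 groups of values checked, where chance alone gives about 20. Coasy was 42.1 CPM in WT_alpha3 54 (the others at most 40.3), Unc45a 91.8 CPM in KO_alpha3 50 (103 to 105), Rab3gap1 31.4 CPM in WT_alpha3 79 (38.2 to 39.3), and Zfp932 26.4 CPM in KO_alpha3 50 (the others 14.7 to 16.5). Kpna3 was 114 CPM in KO_alpha3 50 (125 to 127) and 121 CPM in KO_beta 411 (116 to 117). Csf1r, a macrophage receptor, was 20.5 CPM in KO_beta 411 (27.6 to 29.0), where the macrophage list had a mean log2 CPM of 2.36 (2.92 to 2.96). Pf4, another gene of that list, was 19.97 CPM in WT_beta 399 (4.01 to 6.16), and the X-linked Eif2s3x was 363 CPM in the same library (318 to 321). Gm3893 was 33.0 CPM in KO_beta 402 (18.9 to 20.4). The axon regeneration list had a mean log2 CPM of 5.42 in WT_alpha3 79 (5.84 to 5.92). The liver gene Alb was 142 CPM in WT_alpha3 79, 1741 CPM in WT_beta 399 and 216 CPM in KO_beta 398 (the others of each group at most 38.2, 120 and 36.8), and the sympathetic gene Dbh was 64.5 CPM in WT_beta 401. Alb and Dbh were added to this check after their high values had been seen, so their 4 cases were not found by the check alone. Their CPM is relative here to the counts of the genes kept by the filter and beside the lists to those of all genes, which moves the values by less than 1%.

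The knockout effects of the 2 lines differed for Kpna4, by -6.41 on the log2 scale, and for the sex-linked list, by a median of -9.26. KO_beta and WT_alpha3 libraries all had Y-linked reads, WT_beta libraries had none, and KO_alpha3 had 2 of each kind.

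The libraries spread within groups between progenitor and nociceptor genes, most widely in the α3 line. Sex is argued against in WT_alpha3, whose libraries all had Y-linked reads and spanned 100% of the range of the first principal component. In KO_alpha3 sex stays open, since it divides the libraries as the spread does. There 42 and 81, without Y-linked reads, lay at 4.86 and 4.92 on the progenitor list, and 50 and 75, with them, at 3.53 and 4.04. Spinal cord tissue is argued against in KO_alpha3 42 and 81, whose spinal cord list lay at -0.42 relative to 12 libraries with lower progenitor values (SD 1.07), but stays open for WT_alpha3 45 and 79 at 1.67, where Foxp2 (23.4 and 35.5 CPM) and Pax2 (11.8 and 23.1 CPM) led the 23 measured genes, of which 3 were at 1 CPM or more in every library and 0 belong to another list. A candidate explanation is embryo maturity: the log2 ratio of the early globin Hbb-bh1 to Hbb-y, which falls as primitive red cells mature and is not made by the ganglion, followed the progenitor list in the α3 line (r = 0.95, exact permutation p = 0.00263, n = 8). In the β line r was 0.093 (exact permutation p = 0.806, n = 8), which leaves maturity open there, since 8 libraries are too few to exclude a relation.

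Kpnb1 was higher in KO_beta, at 0.28 ± 0.10 on the log2 scale, with the lowest KO_beta library above 7 of the 8 wild types. With the globin ratio as a covariate the difference was 0.37 ± 0.062 (0.38 ± 0.061 with the progenitor list, 0.39 ± 0.063 with the cell cycle list), which argues against maturity as the globins measure it. Between KO_beta and WT_alpha3, all with Y-linked reads, it was 0.23 ± 0.12 without a covariate and 0.37 ± 0.074 with the progenitor covariate, and a Y-linked covariate over the 8 wild types left 0.32 ± 0.11 (0.72 ± 0.16 against own wild types, where sex divides the libraries as the groups do), and both covariates 0.40 ± 0.067. Both values with the progenitor covariate lay above 0.1 by more than 2 SE. The Y-linked covariate alone narrowly missed this, and KO_beta against WT_alpha3 without a covariate missed it by more. Sex is thus argued against only with the progenitor covariate, which was chosen after the data were seen, and stays open without it. The gene did not pass in edgeR over all genes with the globin covariate (Benjamini-Hochberg adjusted p = 0.402, and 0.000211 to 1 over the alternatives tried, the lowest in DESeq2 with the progenitor covariate), and the deletion, which the design names, stays open as untested, and so do litter and batch, which carry no label.

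The 3 genes that set the wild types of the lines apart did not follow sex. KO_beta, with Y-linked reads, differed from WT_beta, without them, by at most 0.34 on the log2 scale in the 3 genes. The knockouts, which were not compared to choose the genes, also separated by line: in 3 of 3 genes the 4 KO_alpha3 libraries did not overlap the 4 KO_beta libraries, as in 2.86% of random splits per gene. So a batch and the genetic background of the lines cannot be told apart, since both would separate the same libraries. Gm3893 is a pseudogene, and reads shared with other copies were not tested.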

How the results depend on the processing

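The settings with a progenitor covariate, surrogate variables, libraries chosen by Y-linked reads, 4 libraries left out, or locus counts at an unadjusted p under 0.01 were chosen only after the data were seen, and the others were planned. Kpna4 passed in the α3 comparison and in the difference of effects under every setting run, at -6.62 to -6.33 and -6.54 to -6.24 on the log2 scale over the fits that left out 1 library. No number is shared between groups and litters are not labelled, so no paired analysis could be run. For every change below, the cause was not tested.

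The α3 comparison, with 1 call, gave 9 with the wild types of the other line, 4 with the mean of the wild-type groups and 128 with DESeq2. The 9 and the 4 each include Gm3893 and 1500015A07Rik, which were called between the wild types of the lines. It gave 3 with the progenitor covariate, 6 with that and the Y-linked covariate, and 436 with the progenitor covariate in DESeq2. DESeq2 without the 4 libraries highest in other cell types gave 178. The libraries without Y-linked reads, KO_alpha3 42 and 81 against WT_beta, gave 692, and those with them, against WT_alpha3, gave 1. Leaving out 1 library gave 1 to 124, the highest without KO_alpha3 50. The β1 comparison, with 0 calls, gave 4 with the wild types of the other line, 2 with the mean of the wild-type groups, 7 with the β line alone, 1 with DESeq2, 1 with the progenitor covariate in DESeq2, and 0 to 0 leaving out 1 library. Of the 4, 3 were the genes called between the wild types of the lines, and both of the 2 were among those. The 7 were sex-linked genes. The wild types, with 3 calls, gave 5 with the Y-linked covariate, 29 with DESeq2, 6 with the progenitor covariate, 19 with 2 surrogate variables, 321 without the 4 libraries highest in progenitor genes, and 2 to 3 leaving out 1 library. The difference of effects, with 1 call, gave 2 without a filter, 6 with DESeq2, 7 with 2 surrogate variables, 5 without the 4 libraries highest in progenitor genes, and 1 to 3 leaving out 1 library, with 3 without KO_alpha3 50 and 2 without KO_alpha3 75. Apart from Kpna4, every gene called in these settings was X- or Y-linked.

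Kpnb1 passed at 0.50 in the α3 comparison in the libraries without Y-linked reads, KO_alpha3 42 and 81 against WT_beta. Those with Y-linked reads, against WT_alpha3, gave -0.039. In the β1 comparison Kpnb1 passed at 0.37 with the progenitor covariate in DESeq2. Leaving out 1 library gave 0.16 to 0.35 in the α3 comparison and 0.24 to 0.31 in the β1 comparison. At an unadjusted p under 0.01 the knockouts shared 12 genes, or 1 against own wild types. Near Kpna4, 8 genes were counted within 20 Mb, 3 within 10 Mb, 23 within 40 Mb and 6 against own wild types, and near Kpnb1, 1 within 20 Mb and 2 within 40 Mb.

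For the lists below, medians are of differences in log2 CPM, the scale of camera. The lists named are those where camera's direction reversed and the list passed before or after the change. With the Y-linked covariate, which divides the β line as its groups do, the medians in the difference of effects went from 0.066 to -0.26 for nucleoporins, -0.16 to 1.12 for nociceptor, -0.15 to 0.44 for mechanoreceptor, 0.25 to -1.07 for progenitor, -0.20 to 0.50 for glial, 0.32 to -0.86 for cell cycle, 0.11 to -0.28 for ribosomal, 0.017 to -0.079 for respiratory chain, -0.24 to 0.58 for channel, -0.74 to 1.77 for skeletal muscle, -0.078 to 0.66 for fibroblast, -0.058 to 0.65 for macrophage and -11.30 to 0.11 for sex-linked genes. The sex-linked median went from 3.97 to -0.096 in the β1 comparison and from 7.33 to -0.15 in the wild types with this covariate, and from -0.037 to -3.67 in the α3 comparison against own wild types. Without WT_alpha3 79 the wild-type medians went from 0.065 to -0.032 for nucleoporins (up to 0.13 over the fits without 1 library), -0.0085 to 0.11 for pan sensory, 0.23 to 0.025 for progenitor (up to 0.54), 0.14 to -0.24 for cell cycle (up to 0.41) and 0.048 to -0.071 for ribosomal genes (up to 0.14). In the β1 comparison the respiratory chain median went from -0.0078 to -0.074 without KO_beta 406 (up to 0.014 over the fits without 1 library), and the ribosomal median from -0.083 to -0.0059 without KO_beta 411 (down to -0.16). Ccnd1 in the α3 comparison, by fold change, went from -0.64 to 0.69 in DESeq2 without the 4 libraries highest in other cell types. Of the other values of named genes, 4505 stayed on the same side of the threshold, 101 came to pass and 8 no longer passed. The 4505 include any values that changed sign without passing before or after the change.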

Other observations

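The relation of the list means to the globin ratio and the counts of other splits were chosen only after the results had been seen, and the lists themselves were planned.

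Globin genes of red cells varied between libraries of a group. Hbb-y, an embryonic β-like globin gene, was 912 ± 571 CPM in KO_alpha3, 2438 ± 2618 in WT_alpha3, 1151 ± 909 in KO_beta and 622 ± 330 in WT_beta (SD, n = 4 each). Hbb-bh1 was 0.780% of Hbb-y in KO_beta 411 and 7.64% in KO_alpha3 81. Over all 16 libraries the log2 ratio of Hbb-bh1 to Hbb-y followed the progenitor list (Pearson r = 0.849, Spearman rho = 0.782, permutation p = 0.00017 and 0.00064), the nociceptor list (r = -0.902, rho = -0.874, permutation p = 1e-05 and 3e-05) and the cell cycle list (r = 0.935, rho = 0.941, permutation p = 1e-05 for both, the smallest that 100000 resamples can give). After Benjamini-Hochberg adjustment over these 3 relations the values were 0.00017, 1.5e-05 and 1.5e-05 for r and 0.00064, 4.5e-05 and 3e-05 for rho. Without KO_alpha3 81 and WT_alpha3 79, which lay farthest out, r was 0.735, -0.814 and 0.960.

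Within the lines the 3 relations parted. In the α3 line r was 0.946, -0.945 and 0.939 (exact permutation p = 0.00263, 0.00149 and 0.00193, n = 8, adjusted 0.00263 for each), with rho of 0.857, -0.881 and 0.857 (exact permutation p = 0.0107, 0.00724 and 0.0107), and 0.971, -0.937 and 0.991 for r without KO_alpha3 81 and WT_alpha3 79. In the β line the cell cycle list kept the relation (r = 0.930, exact permutation p = 0.000174, adjusted 0.000521, rho = 0.976, n = 8), and r without WT_beta 399 and KO_beta 411 was 0.704. The nociceptor list gave r = -0.511 (exact permutation p = 0.198, adjusted 0.297, rho = -0.643, n = 8) and the progenitor list r = 0.0934 (exact permutation p = 0.806, rho = 0.0952, n = 8), or -0.275 and 0.243 without these 2 libraries. The pooled relations of the progenitor and nociceptor lists were thus not detected within the 8 libraries of the β line.

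Other splits of the samples were counted for each comparison. In the α3 comparison 5 of 100 splits gave at least the 1 real call, with 4081 in the highest other split, for the wild types 2 of 35 gave at least the real 3, with 2307 in the highest other, and for the difference of effects 6 of 100 gave at least the real 1, with 4538 in the highest other. By the number of calls alone chance was not excluded in these comparisons, but a number does not say which gene was called, and Kpna4 had its own exact permutation test in the α3 comparison (p = 0.00202). The β1 comparison had 0 calls, so all 100 of 100 splits gave at least as many and the count tests nothing there; its highest other split gave 4371. Splits with so many more calls point to a structure of the samples, and the highest in the wild types put WT_alpha3 45 and 79 with WT_beta 399 and 401.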
